A study of Mus musculus with 6 samples.

How the data were processed

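Messenger RNA was sequenced from C2C12 myotubes, a mouse muscle cell line that fuses into multinucleated fibres when serum is withdrawn. Per the labels' protocols, poly(A) RNA was selected, libraries were made with a NEBNext Ultra kit, and the 3 libraries of each treatment came from independent biological replicates. The authors deposited 1 table of raw read counts per gene, with 1 column for each of the 6 libraries. The submitters' processing notes name HISAT2 2.0.5, HTSeq 0.6.1, DESeq2 1.24.0 and the mouse build mm10, without saying which settings were used. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. The kit is not stated to mark strand, so reads from overlapping or antisense genes cannot be told apart in these counts, and reads shared between near-identical genes may be split or lost.

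The counts were used as deposited. The table held 46983 genes, and every row named a gene. Of the gene identifiers, 46488 (98.95%) matched GENCODE M21, which annotates the GRCm38 assembly (mm10), and biotypes, exon lengths and coordinates were taken from it. Total counts ran from 23877583 to 29928653 per library. A count of 3, taken as the floor, equalled 0.100 to 0.126 CPM (counts scaled to a common library size), and covers counting error alone.

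Corticosterone was compared with vehicle by edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM scaling, on the 14450 genes kept by filterByExpr. The test was two-sided, with Benjamini-Hochberg adjustment over those genes and a threshold of 0.05. CPM values given for a gene are TMM-scaled, means carry the SD, and fold changes are corticosterone minus vehicle on the log2 scale. No replicate block was used. 29 gene lists, written before the data were examined, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjustment was over the lists with at least 5 genes kept. An estimated correlation and fry were run beside it. Library totals, the share of counts from mitochondrially encoded genes and the share from the 10 most abundant genes were compared by exact two-sided permutation tests, for which 3 against 3 libraries allow no p under 0.1.

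On counts simulated for these 14450 genes with 200 genes changed, edgeR found 31.4% of 70 genes changed 1.5-fold, 70.0% of 70 genes changed 2-fold and 96.7% of 60 genes changed 4-fold, with 10 false calls. DESeq2 found 51.4%, 81.4% and 96.7%, with 45 false calls. With no gene changed, edgeR made 2 calls, and 4.78% of genes had an unadjusted p under 0.05. Each gene was simulated independently, without groups of similar libraries or libraries out of place, and the changed genes were not taken from the least abundant. These rates need not hold for the real libraries, in which 11.8% of genes had an unadjusted p under 0.05.

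The genes to be named were fixed by a rule before the data were examined. It named 14 genes of glucocorticoid action and muscle atrophy whatever their values, and up to 8 called genes per direction with no overlap between groups and a mean of at least 5 CPM. For each list it named up to 3 called members or, where none was called, the 2 with the highest mean CPM. No gene met the part of the rule that needs a call. Genes chosen after their values were seen are said to be so.

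The alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings, a looser and a stricter count filter, protein-coding genes only, replicate number as a block, gene-length offsets (loess span 0.5), a minimum fold of 1.2 and each library left out in turn. Leaving out pairs of libraries, 1 from each group, was added after the values were seen. No column was left unmapped and no library was left out of the main comparison.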

Results

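Gene expression was measured by RNA sequencing in C2C12 myotubes after 24 h with corticosterone at 1e-07 M, the main glucocorticoid of rodents, or with ethanol vehicle at 1 µL/mL. There were 3 libraries per treatment, described by the submitters as independent biological replicates. The question was which genes differ between corticosterone-treated and vehicle-treated myotubes. Total counts were 29007179, 29928653 and 25826081 in the libraries labelled corticosterone replicates 1, 2 and 3, and 24901830, 28496898 and 23877583 in those labelled vehicle replicates 1, 2 and 3. Between 19541 and 20404 genes had at least 1 count in a library.

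Genes that glucocorticoids are known to induce were read first, because they check the labels, and in 2 libraries several of them went against the labels. Fkbp5, a co-chaperone of the glucocorticoid receptor (ENSMUSG00000024222, GRCm38 chromosome 17, 28399094 to 28517527), stood at 151, 36.9 and 135 CPM in the libraries labelled corticosterone replicates 1, 2 and 3. In those labelled vehicle replicates 1, 2 and 3 it stood at 36.9, 177 and 35.4 CPM. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), gave 218, 65.1 and 232 CPM against 67.0, 264 and 76.2 CPM. Per1, a clock gene with glucocorticoid response elements (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960), gave 85.2, 36.5 and 88.9 CPM against 31.6, 76.0 and 35.1 CPM. Thus the library labelled corticosterone replicate 2 had the lower level of these 3 genes, near that of the libraries labelled vehicle replicates 1 and 3, and the library labelled vehicle replicate 2 had the higher level. Glul, which encodes glutamine synthetase, gave 334, 136 and 293 CPM against 173, 349 and 167 CPM, and Mt2, a metallothionein, gave 84.9, 3.29 and 103 CPM against 57.8, 163 and 6.05 CPM. Not all members of the list went against the labels in this way. Gadd45g, a growth arrest gene and the 1 member of 27 without overlap between the labels, gave 78.05, 103.8 and 113 CPM against 66.1, 72.9 and 75.1 CPM. Nfkbia, which encodes an inhibitor of NF-kB, gave 27.7, 32.3 and 44.7 CPM against 22.0, 27.7 and 20.04 CPM, and Ddit4, an inhibitor of mTOR signalling, 34.3, 47.9 and 58.4 CPM against 30.5, 30.8 and 36.0 CPM. Both overlapped between the labels, with corticosterone replicate 2 above every library labelled vehicle. Cdkn1a and Rhob, the members with the highest CPM, were named by the rule. Cdkn1a gave 2470, 2846 and 2745 CPM against 1935, 2004 and 2664 CPM, highest in corticosterone replicate 2. Rhob varied little, at 704, 647 and 698 CPM against 639, 658 and 702 CPM. Of the 27 members tested, 5 were higher in corticosterone replicate 2 than in every library labelled vehicle, and 14 were higher in vehicle replicate 2 than in every library labelled corticosterone. Glul, Mt2, Gadd45g and Nfkbia were chosen after their values were seen.

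**Figure D1:**
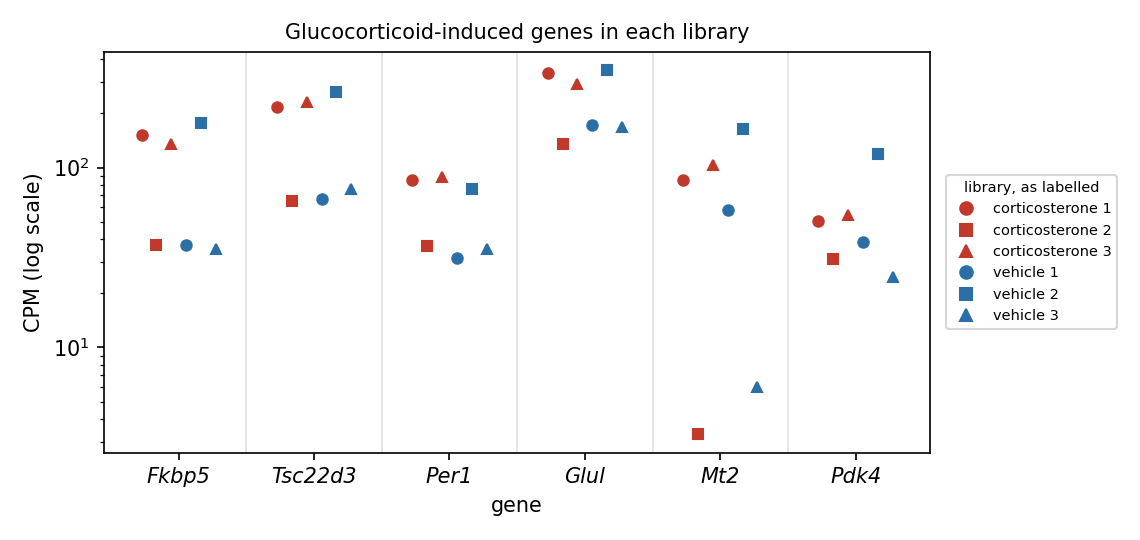
CPM on a log axis of 6 glucocorticoid-induced genes, with 1 point per library, coloured by the label and shaped by the replicate number. All 6 go against the labels in the libraries numbered 2. Cdkn1a, Ddit4, Gadd45g and Nfkbia, in which corticosterone replicate 2 lay above every library labelled vehicle, are not shown. The library labelled corticosterone replicate 2 lies at 36.9 CPM for Fkbp5 and the library labelled vehicle replicate 2 at 177 CPM, the reverse of their labels; Pdk4 was, like Glul and Mt2, chosen after its values were seen.

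By the labels, Fkbp5, Tsc22d3 and Per1 therefore did not separate the treatments. Fkbp5 was 108 ± 61.9 CPM (SD, n = 3) in the libraries labelled corticosterone and 83.2 ± 81.5 CPM (SD, n = 3) in those labelled vehicle, a log2 difference of 0.37 ± 0.73 (SE, edgeR adjusted p = 0.852). Tsc22d3 differed by 0.34 ± 0.63 (adjusted p = 0.843) and Per1 by 0.56 ± 0.42 (adjusted p = 0.61). With 1 library left out, the differences ran from -0.001 to 1.57 (Fkbp5), 0.004 to 1.26 (Tsc22d3) and 0.33 to 1.07 (Per1). Of the 27 genes tested in the list of canonical glucocorticoid-induced genes, 0 passed over all genes and 0 when adjusted over the list alone. 16 lay higher and 11 lower in the libraries labelled corticosterone, with a median log2 difference of 0.06, and the list was not called as a set (camera adjusted p = 0.397, and adjusted p = 0.948 with an estimated correlation). The list was called without corticosterone replicate 2 (median 0.19, adjusted p = 0.0198, and adjusted p = 0.888 with an estimated correlation) and without vehicle replicate 2 (median 0.25, adjusted p = 0.00752, and adjusted p = 0.864 with an estimated correlation). The median turned to -0.006 without corticosterone replicate 1, -0.03 without vehicle replicate 1 and -0.046 without vehicle replicate 3, and the list was then not called. With both libraries numbered 2 left out, the median was 0.41 and the adjusted p was 8.9e-08 (adjusted p = 0.612 with an estimated correlation). Those libraries were left out because of these same genes, so this is not independent evidence of a direction. The first 14 genes of the naming rule include the receptor gene Nr3c1, at 98.4 ± 12 against 105.5 ± 13.4 CPM (SD, n = 3 each), and Hsd11b1, which regenerates active glucocorticoid, at 53.9 ± 18.5 against 78.4 ± 37.8 CPM. Neither passed (adjusted p = 0.748 and 0.61). Hsd11b1 overlaps Lamb3, and reads of the overlap cannot be assigned to either without strand. The list of corticosteroid receptors, chaperones and metabolism had 0 of 18 genes passing, and its most abundant member, Hsp90ab1, stood at 2980 ± 136 against 2677 ± 128 CPM (adjusted p = 0.535; list adjusted p = 0.266).

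Over all 14450 genes, 0 passed the edgeR test, 0 higher and 0 lower, and the smallest adjusted p was 0.364. At an unadjusted p under 0.05 there were 1707 genes, 802 higher and 905 lower in the libraries labelled corticosterone. limma-voom called 0 genes and DESeq2 called 138, of which 68 were higher and 70 lower. CPM did not overlap between the labels for 2398 genes (16.6%), where chance gives 10%. Other splits of the libraries into 3 and 3 separated from 404 to 2548 genes. Among protein-coding genes without overlap, those with the smallest p in each direction, chosen after their values were seen, were 1700047I17Rik2 and Apaf1, higher, and Fam64a and Kng2, lower. Apaf1, the scaffold of the apoptosome, stood at 31.5 ± 2.70 against 20.3 ± 2.13 CPM, a log2 difference of 0.64 ± 0.11 (SE, adjusted p = 0.364, and 0.00495 by DESeq2). Fam64a, a gene of mitosis, stood at 6.57 ± 0.57 against 13.9 ± 2.53 CPM, a log2 difference of -1.07 ± 0.16 (adjusted p = 0.364, and 1.04e-04 by DESeq2). 1700047I17Rik2 differed by 1.61 ± 0.21 and Kng2 by -1.22 ± 0.20 on the log2 scale.

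The count of 0 depended on single libraries. Without the library labelled corticosterone replicate 1 there were 29 calls, 7 higher and 22 lower, and without that labelled vehicle replicate 3 there were 11, 9 higher and 2 lower. With both libraries numbered 2 left out, which was decided on the values of Fkbp5, Tsc22d3 and similar genes, 3 genes were called, all higher: Fkbp5 (log2 difference 1.98 ± 0.12, adjusted p = 0.0307), Ctla2a (3.63 ± 0.23, adjusted p = 0.0307) and Tsc22d3 (1.65 ± 0.12, adjusted p = 0.0478). Ctla2a, which encodes a cysteine protease inhibitor, stood at 254, 14.1 and 264 CPM in the libraries labelled corticosterone and at 25.5, 620 and 16.3 CPM in those labelled vehicle, and was chosen after its values were seen. Of the other 8 pairs of 1 library from each label, leaving out corticosterone replicate 1 with vehicle replicate 3 gave 575 calls, and the remaining 7 gave 0 to 2. The fit with 575 calls set corticosterone replicates 2 and 3 against vehicle replicates 1 and 2, 2 pairs of libraries that lay near each other. Each side then held 1 library with the higher and 1 with the lower level of Fkbp5 (36.9 and 135 against 36.9 and 177 CPM). Those calls therefore cannot be told apart from differences between cultures.

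Lists of 5 gene groups were called as sets with the preset correlation, none of them with the estimated correlation. Genes of the cell cycle, a marker of proliferating myoblasts among the myotubes, were lower in the libraries labelled corticosterone: 26 of 27 genes had a negative log2 difference, with a median of -0.30 (camera adjusted p = 7.38e-08, and adjusted p = 0.948 with an estimated correlation). The list medians were -0.17, -0.17 and -0.07 log2 units from the mean of the 6 libraries in those labelled corticosterone replicates 1, 2 and 3, and 0.25, 0.18 and -0.05 in those labelled vehicle. Vehicle replicate 3 thus lay beside corticosterone replicate 3, and vehicle replicates 1 and 2, which the first principal component set apart, lay highest. No member passed the edgeR test over all genes, and 3, chosen after their values were seen, passed when adjusted over the list alone. These were Ccna2, which encodes cyclin A2, at 21.1 ± 1.16 against 29.3 ± 1.70 CPM (log2 difference -0.47 ± 0.09), Top2a, a topoisomerase of dividing cells, at 57.6 ± 0.79 against 71.5 ± 3.01 CPM (-0.31 ± 0.07), and the mitotic kinesin gene Kif11 at 14.2 ± 0.65 against 19.7 ± 2.13 CPM (-0.47 ± 0.11). DESeq2 called Ccna2 and Top2a over all genes (adjusted p = 0.0137 and 0.0398) and did not call Kif11 (adjusted p = 0.0533). Ccna2 overlaps Exosc9, so its counts may hold reads of that gene. The CPM of these 3 genes did not overlap between the labels, nor did that of 10 list members in all, where 16.6% of all genes tested did not overlap. The members with the highest CPM, Rrm2 and Pcna, differed by 0.12 ± 0.21 and -0.17 ± 0.15.

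Mitochondrially encoded genes were higher as a set, with 12 of 12 log2 differences positive and a median of 0.30 (adjusted p = 0.00277, and adjusted p = 0.948 with an estimated correlation), but 0 of 12 passed singly or when adjusted over the list alone. mt-Co1 stood at 10350 ± 331 against 8648 ± 2470 CPM. The share of counts from these genes was 2.53, 2.46 and 2.39% in the libraries labelled corticosterone and 1.69, 1.67 and 2.76% in those labelled vehicle (exact permutation p = 0.4). The library labelled vehicle replicate 3 had the highest share. The list's median was 0.13 without vehicle replicate 1, 0.19 without vehicle replicate 2 and 0.55 without vehicle replicate 3. Without corticosterone replicate 1 the median was 0.24 and the call was lost (adjusted p = 0.0604).

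Proteasome subunit genes had 27 of 32 log2 differences positive, with a median of 0.08 (adjusted p = 0.00535, and adjusted p = 0.948 with an estimated correlation), and 0 passed singly or over the list alone. Psmd2 stood at 533 ± 3.08 against 472 ± 27.4 CPM (adjusted p = 0.436). The call was lost without corticosterone replicate 3 (median 0.051, adjusted p = 0.201) and without vehicle replicate 3 (median 0.063, adjusted p = 0.0529). Genes of excitation-contraction coupling and calcium handling had 17 of 19 positive, with a median of 0.14 (adjusted p = 0.0212, and adjusted p = 0.948 with an estimated correlation), and 0 passed singly or over the list alone. Their most abundant member, the calcium pump gene Atp2a2, differed by 0.08 ± 0.13. That call was lost without corticosterone replicate 1 (median 0.033, adjusted p = 0.685) and without vehicle replicate 1 (median 0.044, adjusted p = 0.258), and without corticosterone replicate 2 the median was 0.23.

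Extracellular matrix and fibrosis genes had 25 of 32 log2 differences positive, with a median of 0.26 (adjusted p = 0.0107, and adjusted p = 0.948 with an estimated correlation). None passed the edgeR test over all genes and 2, chosen after their values were seen, passed when adjusted over the list alone: the collagen VI gene Col6a3, at 389 ± 59.0 against 143 ± 72.5 CPM (log2 difference 1.44 ± 0.32), and the collagen V gene Col5a1, at 1305 ± 212 against 873 ± 39.2 CPM (0.58 ± 0.13). DESeq2 called Col5a1 over all genes (adjusted p = 0.011) and did not call Col6a3 (adjusted p = 0.0758), and edgeR called Col6a3 without vehicle replicate 3 (log2 difference 1.93, adjusted p = 0.0314). The most abundant members, Fn1 and Thbs1, differed by 0.13 ± 0.29 and 0.22 ± 0.32, and both were highest in the library labelled corticosterone replicate 2, at 11394 and 8210 CPM. The list's call was lost without corticosterone replicate 2 (median 0.20, adjusted p = 0.121) and without vehicle replicate 3 (median 0.19, adjusted p = 0.225), and without corticosterone replicate 1 the median was 0.43. The 5 lists kept their direction under each of the 4 scalings.

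**Figure D2:**
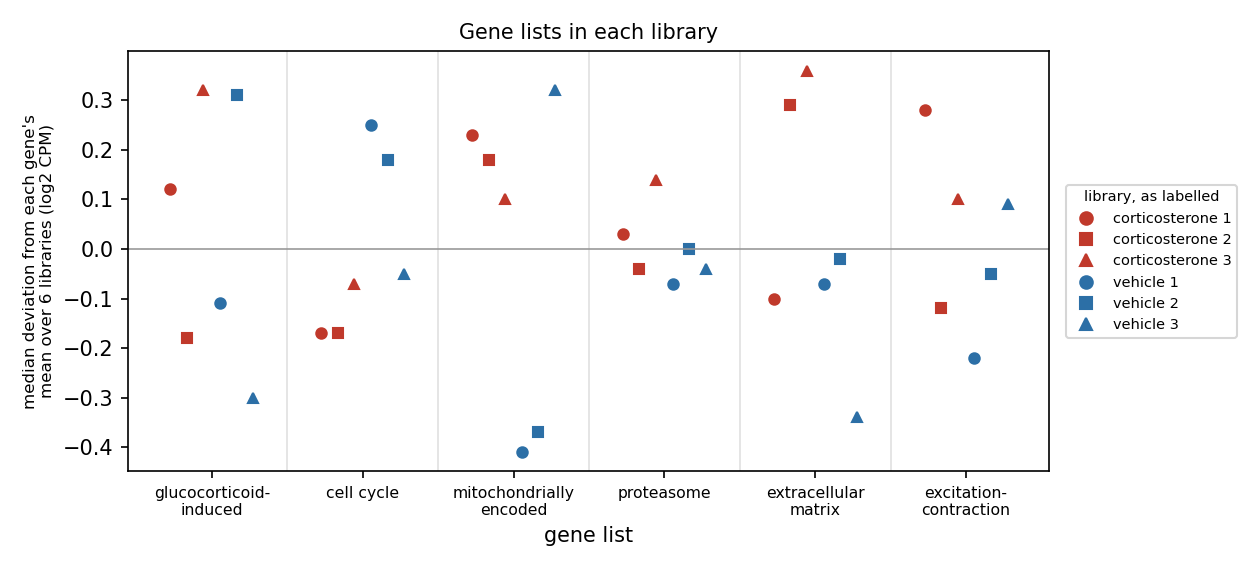
Median over each list's genes of the deviation from the gene's mean over the 6 libraries, in log2 CPM, with 1 point per library, coloured by the label and shaped by the replicate number. For the mitochondrially encoded genes the library labelled vehicle replicate 3 lies at 0.32, above the libraries labelled corticosterone, and for the glucocorticoid-induced genes the libraries numbered 2 lie at -0.18 and 0.31 for corticosterone and vehicle.

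Of the muscle atrophy genes, 0 of 23 passed, 8 lay higher and 15 lower, and the list was not called (adjusted p = 0.648). The ubiquitin ligase genes Trim63 and Fbxo32, whose products act in muscle wasting, stood at 59.3 ± 3.27 against 51.8 ± 8.77 CPM and at 145 ± 11.9 against 138 ± 32.5 CPM (adjusted p = 0.566 and 0.881). The transcription factor genes Foxo1 and Foxo3 differed by 0.02 ± 0.11 and 0.04 ± 0.11, Klf15 by -0.42 ± 0.69 and Ddit4 by 0.53 ± 0.18 (adjusted p = 0.37). Klf15 was lowest in corticosterone replicate 2 (0.55 CPM) and highest in vehicle replicate 2 (4.93 CPM). Its difference thus rests on the 2 libraries whose labels are in doubt. Fbxo32 was also highest in vehicle replicate 2 (176 CPM). Unlike Klf15, it was higher in corticosterone replicate 2 (158 CPM) than in corticosterone replicates 1 and 3 (137 and 138 CPM). Foxo1 went the other way from Klf15, at 62.8 CPM in corticosterone replicate 2 and 48.6 CPM in vehicle replicate 2. Mstn, which encodes myostatin, was under the count filter, with counts of 9, 23 and 31 in the libraries labelled corticosterone and 4, 3 and 2 in those labelled vehicle. In the insulin, IGF and mTOR list 0 of 34 passed (adjusted p = 0.969). Igf1 gave 141 ± 58.0 against 146 ± 68.8 CPM and Pik3r1 150 ± 30.4 against 137 ± 40 CPM. Igfbp5, the most abundant member, differed by -0.43 ± 0.26, with its lowest value in corticosterone replicate 3 and its highest in vehicle replicate 1. Deptor, the other member that the rule named, differed by 0.05 ± 0.32. It was lowest in corticosterone replicate 2 and highest in vehicle replicate 2, at 466 and 1016 CPM.

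No gene passed in the other muscle lists, and none was called as a set with all 6 libraries. Sarcomere and myofibril genes had 26 of 40 higher (adjusted p = 0.266), and Acta1, skeletal muscle actin, stood at 4651 ± 177 against 4079 ± 474 CPM. Myogenic regulators and fusion genes had 15 of 18 higher (adjusted p = 0.266), with Myog at 791 ± 44.0 against 723 ± 124 CPM. Neuromuscular junction genes had 11 of 16 higher (adjusted p = 0.31). The sarcomere list, with a median of 0.105, was called without corticosterone replicate 2 (median 0.20, adjusted p = 6.4e-04, and adjusted p = 0.888 with an estimated correlation) and without vehicle replicate 3 (median 0.25, adjusted p = 0.0168, and adjusted p = 0.968 with an estimated correlation). Its median fell to -0.003 without corticosterone replicate 1 and to 0.023 without vehicle replicate 1. The myogenic list was called without corticosterone replicate 2 (median 0.13, adjusted p = 0.0131, and adjusted p = 0.888 with an estimated correlation). In metabolism, the adjusted p was 0.31 for glycolysis and glycogen (28 genes), 0.474 for fatty acid uptake, storage and oxidation (28 genes), 0.928 for cholesterol and fatty acid synthesis (30 genes), 0.648 for nuclear oxidative phosphorylation subunits (73 genes) and 0.843 for amino acid transport and metabolism (20 genes). It was 0.266 for autophagy and lysosome (29 genes), 0.862 for the unfolded protein and ATF4 response (25 genes) and 0.388 for antioxidant and metallothionein genes (18 genes). Glycolysis was called without corticosterone replicate 2 (median 0.15, adjusted p = 0.00831) and nuclear oxidative phosphorylation without corticosterone replicate 3 (median -0.053, adjusted p = 0.0369), with adjusted p = 0.888 and 0.95 with an estimated correlation. The glycolysis median was 0.07 with all libraries and 0 without corticosterone replicate 1. Without vehicle replicate 2, cholesterol synthesis (median -0.11, adjusted p = 0.0184) and the unfolded protein response (median -0.13, adjusted p = 0.0391) were called, both with adjusted p = 0.864 with an estimated correlation.

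For inflammation and NF-kB the adjusted p was 0.266 (20 genes, median 0.11). The list was called without corticosterone replicate 1 (median 0.18, adjusted p = 0.0366, and adjusted p = 0.965 with an estimated correlation) and without vehicle replicate 1 (median 0.13, adjusted p = 0.033, and adjusted p = 0.937 with an estimated correlation). The median fell to -0.001 without corticosterone replicate 2, 0.064 without corticosterone replicate 3 and 0.029 without vehicle replicate 2. The list's member Nfkb2 stood at 161 ± 19.6 against 118 ± 15.6 CPM without overlap (adjusted p = 0.364). The adjusted p was 0.969 for interferon-stimulated and antigen presentation genes (23 genes), 0.895 for TGF-beta, activin and BMP signalling (29 genes), 0.474 for the circadian clock (18 genes) and 0.519 for immediate early genes (19 genes). The median and the direction of the set test differed in sign for the insulin, IGF and mTOR list and for amino acid transport. Median and mean differed in sign for those lists, for interferon-stimulated genes and for fatty acid genes. Among markers of other cells, undifferentiated reserve myoblast markers (11 genes, adjusted p = 0.812), adipocyte markers (6 genes, adjusted p = 0.648) and osteoblast and cartilage markers (5 genes, adjusted p = 0.895) were not called. Of the leukocyte and endothelial markers 2 of 12 passed the count filter, too few to test: Cd68 stood at 1.45 ± 0.50 against 1.14 ± 0.34 CPM and Tek at 0.46 ± 0.09 against 0.59 ± 0.06 CPM. In each of these lists 0 genes passed, over all genes or adjusted over the list alone.

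Over the 9835 genes with a mean log2 CPM above 3, the libraries lay in 3 near pairs. The library labelled corticosterone replicate 1 lay nearest to that labelled vehicle replicate 3, at a root mean square log2 difference of 0.216, and vehicle replicates 1 and 2 lay 0.215 apart. Corticosterone replicates 2 and 3 lay 0.261 apart, and the other distances ran from 0.294 to 0.374. Each near pair held 1 library with the higher and 1 with the lower level of Fkbp5. The first principal component took 39.0% of the variance and set vehicle replicates 1 and 2 (18.3 and 17.1) apart from the other 4 libraries (-13.0 to -6.29). Total counts averaged 28250000 ± 2150000 in the libraries labelled corticosterone and 25760000 ± 2430000 in those labelled vehicle (SD, n = 3 each, exact permutation p = 0.2). The 10 most abundant genes took 5.36 ± 0.57% and 4.80 ± 0.26% of counts (exact permutation p = 0.2). No 2 libraries agreed within sampling noise, since the chi-square per degree of freedom was at least 16.6 for every pair.

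**Figure D3:**
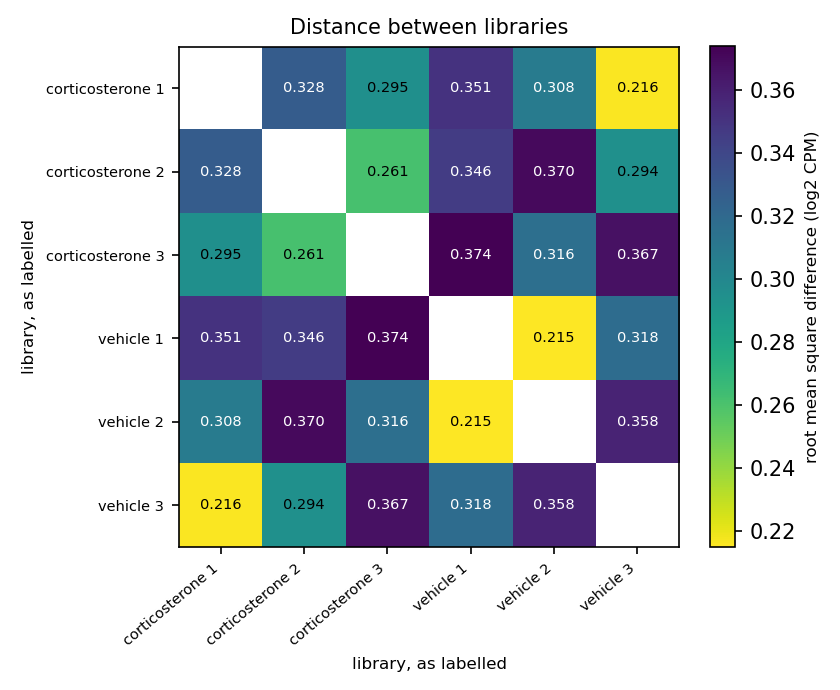
Root mean square difference in log2 CPM between each 2 libraries, named by label and replicate number, over genes with a mean log2 CPM above 3. The lightest cells are the pairs at 0.215 and 0.216, vehicle replicate 1 with 2 and corticosterone replicate 1 with vehicle replicate 3.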

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

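Leaving out pairs of libraries, and the upper-quartile and totals-only scalings of the lists, were chosen after the values were seen. The 0 calls stayed 0 with limma-voom, each other scaling and filter, protein-coding genes, length offsets and the minimum fold. DESeq2 gave 138 (68 higher, 70 lower), and the cause was not tested. Leaving out 1 library gave 0 to 29 calls (higher 0 to 9, lower 0 to 22): 29 without corticosterone replicate 1 and 11 without vehicle replicate 3. Leaving out a pair gave 2 calls for corticosterone 1 with vehicle 1 (1 higher, 1 lower), 2 for corticosterone 1 with vehicle 2 (2 lower), 575 for corticosterone 1 with vehicle 3 (245 higher, 330 lower) and 3 for the pair numbered 2 (3 higher), where fewer samples were fitted. The fit with 575 calls compared 1 near pair of libraries with another, so those calls cannot be put down to corticosterone. Replicate number as a replicate block gave 0 calls, also with length offsets, and left the 5 lists called. Libraries of the same number deviated apart (r = -0.32, -0.38 and -0.46 across genes, which are not independent), so the numbers were not taken as pairs.

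Against 5 lists called, 0 were called with an estimated correlation or by fry, 4 to 8 with 1 library left out, of which 3 to 5 were among the first 5, and 12 without the pair numbered 2, the first 5 among them. With an estimated correlation or by fry, 0 of these calls held in any of those settings, and without the pair the lowest adjusted p was 0.612 and 0.205. The others of the 12 were glucocorticoid-induced genes, corticosteroid receptors, sarcomere, myogenic regulators, cholesterol synthesis, the unfolded protein response and adipocyte markers. The mitochondrially encoded share had a ratio of 1.21, or 1.11 to 1.46 with 1 library left out, highest without vehicle replicate 3. Cholesterol and fatty acid synthesis reversed to a median of -0.20 without the pair numbered 2, and ran from -0.11 to 0.12 with 1 library left out. Of 1495 recomputed fold changes of 88 named genes, 85 changed sign, 19 by more than their standard error or with a call. With the pair left out these became 0.71 (Klf15), -0.15 (Foxo1), 0.12 (Casq2), -0.38 (Fn1), 0.083 (Sdc4), -0.35 (Notch3), 0.28 (Cebpa), 0.66 (Mt1), 1.56 (Mt2), 0.73 (Pdk4) and 3.63 (Ctla2a). Under the block Ctla2a was 2.02, and 2.00 with length offsets too. With 1 library left out the ranges were -0.28 to 0.34 (Fn1), -0.21 to 0.47 (Thbs1), -0.35 to 0.17 (Cebpa), -0.80 to 0.99 (Mt2), -0.80 to 0.52 (Pdk4) and -0.87 to 3.08 (Ctla2a). Other sign changes stayed within the standard error. Mt1 was chosen after its values were seen.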

Other observations

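The tests of the glucocorticoid-induced genes and of the distances between libraries were chosen after the values were seen. Of the counts over splits of the libraries, those of genes called and of lists moved were chosen before. The counts at an unadjusted p, of separated genes and for the cell cycle list, and the grouping of splits by near pairs, were not among those set beforehand. Other groups varied between libraries without following the labels. Genes of cholesterol and fatty acid synthesis had list medians of -0.19, 0.19 and 0.00 log2 units from the mean of the 6 libraries in those labelled corticosterone replicates 1, 2 and 3, and 0.08, -0.26 and 0.15 in those labelled vehicle. Adipocyte markers gave 0.05, -0.27 and 0.34 against -0.12, 0.30 and -0.37, an order of libraries close to that of the glucocorticoid-induced genes (0.12, -0.18 and 0.32 against -0.11, 0.31 and -0.30). Of the adipocyte markers 6 were tested, and some of them also stood in other lists. With genes of more than 1 list removed, too few were left to test. Pdk4, which restrains glucose oxidation, gave 50.2, 31.2 and 54.7 CPM against 38.3, 118 and 24.8 CPM, and Sgk1, a kinase that glucocorticoids induce, gave 134, 109 and 181 CPM against 85.8, 136 and 97.9 CPM. Pdk4 and Sgk1 were chosen after their values were seen.

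Glucocorticoid-induced genes did not follow the labels of corticosterone replicate 2 and vehicle replicate 2, although 5 of the 27 members of the preset list were higher in corticosterone replicate 2 than in every library labelled vehicle. Of the 27, 13 were higher in corticosterone replicates 1 and 3 and vehicle replicate 2 than in every other library, against 1 for the labelled split and at most 3 for any other of the 10 splits, and the highest of 10000 random lists matched on expression was 7. Sequencing depth or scaling as the whole cause is argued against, since 1 factor per library would move other genes of the same expression alike. Those random lists held a median of 1 member so separated. Their genes were drawn 1 by 1, so they lack the correlation between the list's genes. With TMM, RLE, upper-quartile and no scaling, 13, 13, 13 and 12 members of the list were so separated. A disturbance that moved both libraries numbered 2 the same way is argued against by the pattern itself. Each gene's deviation from the mean of the other libraries of its label had a median over the list of -0.27 log2 units for corticosterone replicate 2. For vehicle replicate 2 that median was 0.54 log2 units. A disturbance that moved them in opposite directions stays open. A candidate explanation is that the labels of these libraries were exchanged: with an estimated correlation that split alone of the 10 called a list, these same genes (adjusted p = 0.0273), which proposed the exchange and so are no independent evidence for it; 2 separate dosing errors would put the same 2 libraries out of place and cannot be told apart from it.

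The number of genes changed by corticosterone was 0 with the labelled split, and the highest of the other splits gave 16. The split with 16 exchanges the libraries numbered 2. Fkbp5, Tsc22d3 and similar genes proposed that split, and the 16 were not counted without such genes. The count is therefore no independent evidence for an exchange. That split gave 725 genes at an unadjusted p under 0.05 and separated 1392 genes without overlap of CPM. The labelled split gave 1707 and 2398, where chance separates 10% of genes. The split with vehicle replicate 3 in the place of corticosterone replicate 3 gave the most, 1730 and 2548. Both of these keep near pairs of libraries on 1 side, while the exchanged split divides every near pair. The other splits that divide every near pair gave 54 to 76 genes and separated 404 to 508. The lower counts of the exchanged split therefore do not weigh against an exchange. With 0 genes in the labelled split each of the 10 splits gives as many by construction, so that count says nothing.

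The lists moved as sets numbered 5, and the highest of the other splits gave 12. At least 5 lists moved in 9 of the 10 splits, so the number of lists does not set the labelled split apart from other groupings of the libraries. In any case, 10 splits are too few for a share under 0.05. A candidate explanation for the lists is differences between cultures that the labels do not record: vehicle replicate 3 lay 0.216 log2 units from corticosterone replicate 1, nearer than the 0.318 to the closest vehicle library. The cell cycle list had an adjusted p of 7.38e-08 with the labelled split (adjusted p = 0.948 with an estimated correlation), 4 of the 9 other splits called it, at 1.48e-05 to 0.00654, and 5 did not, at 0.136 to 0.829, so its loss with the libraries numbered 2 exchanged (0.829) is not particular to that split. An effect of corticosterone on these lists stays open. The fit without both libraries numbered 2 divided its only near pair between the sides, and it called these 5 lists in the same direction. For the cell cycle list the median was -0.23 (camera adjusted p = 2.62e-04, and adjusted p = 0.769 with an estimated correlation). That fit had fewer libraries and was chosen after the values were seen, and none of its list calls held with an estimated correlation.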
